A study of Pseudomonas aeruginosa with 47 samples.

How the data were processed

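RNA sequencing of Pseudomonas aeruginosa PA14 was analysed from 47 deposited tables, 1 per library, each holding read counts for 6014 features. Per the labels' protocols, RNA of 3 cultures was pooled for each library, eukaryotic RNA was depleted from the tumor samples and their controls, bacterial ribosomal RNA was depleted, and libraries were made by fragmentation by sonication, barcoded adapters, PCR and normalization with a duplex-specific nuclease. The counts were taken as deposited; the aligner, the counting program, the genome build, the strand setting and the treatment of reads that match several places are not given in the sources used here. The nuclease step acts on abundant molecules, and its effect on the levels was not tested. Features are named by the locus tag and symbol of the deposited tables: 2466 have a symbol, 3548 have none, and 113 symbols stand on several features, which are named with the locus tag. Coordinates were not used here. Levels of near-identical copies (rRNA operons, tufA and tufB, the phz operons, prrF1, prrF2 and prrH) are uncertain.

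Libraries were grouped by the growth condition of the labels into 14 conditions. The titles name an empty vector (11 libraries) or an overexpressed sigma factor (3 libraries), whereas the strain label gives the wild type throughout. The 3 overexpressed titles were kept as 2 groups of their own, which makes 16 groups. The culture label reads planktonic also for biofilm and tumor libraries, and the condition label was used. Total counts, rRNA shares and the level that 3 counts represent are given at the start of the report. The TMM factors ran from 0.132 (biofilm 24 h 1) to 2.95 (anoxic 1).

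Genes were tested with edgeR 4.0.16 (R 4.3.3): low counts were filtered with filterByExpr by group, which kept 5876 features, TMM factors were used with library sizes of all features, and quasi-likelihood F tests of contrasts were taken from 1 fit of all groups. A gene is called at a Benjamini-Hochberg adjusted p under 0.05. The title comparison used the 28 libraries of conditions with both kinds of title, with condition in the model and 5475 features kept. The test across conditions was an F test over 44 libraries. SE is the fold change divided by the root of the F statistic. The p-values measure spread between libraries that each pool 3 cultures, so variation between single cultures is not seen. Counting intervals (95%, exact binomial) and floors (3 counts over the group) cover counting error only.

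Genes named in the report followed a rule. Candidates had a symbol, an adjusted p under 0.05 and a mean of at least 20 CPM over the libraries of both groups together. Every library of the higher group also had to lie above every library of the lower group. Non-overlap of such genes is therefore a condition of their choice and not a finding. Named were the 8 candidates with the largest change per direction, at most 2 per 3-letter stem. Up to 4 called members of each list the comparison is about were added. From the genes so named the text takes those whose function is known. The 34 lists of genes were written from general knowledge of the species and matched by symbol: pyoverdine, pyochelin, heme uptake, other iron uptake, iron storage and iron enzymes, heat shock, AlgU envelope stress, alginate, stationary phase, ribosomal proteins, ATP synthase and NADH dehydrogenase, denitrification, other low-oxygen genes, phosphate starvation, quorum sensing regulators and exoproducts, phenazines, type III and type VI secretion, flagellum, chemotaxis, type IV pili, biofilm matrix and cyclic di-GMP, fatty acid synthesis, osmoadaptation, sulfate limitation, amino acid synthesis, zinc limitation, SOS and pyocins, oxidative stress, tricarboxylic acid cycle, multidrug efflux, sigma factors, and surface attachment. Members without a matching or a tested feature are not counted, which left 4 of 30 type VI secretion symbols and 6 of 23 of surface attachment. Lists were tested with camera (limma 3.58.1), applied to the counts through edgeR's own method (preset correlation of 0.01). The p-values were adjusted over 510 tests of 34 lists and 15 comparisons, with an estimated correlation and fry as alternatives.

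Groups, comparisons, reference groups, lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were RLE and upper quartile factors, no filter, rRNA and tRNA left out, DESeq2 1.42.0, fits of the 2 groups alone, a replicate block, other reference groups, titles left out or merged, and each library left out in turn. Added after seeing the data were a fit of the titles within iron starvation with the experiment as a block, fits without transitional growth replicates 2 and 6 or without 1, 3 and 4, and, for the anoxic libraries, fits without rRNA, tRNA, tuf and phz operon genes and a count of phenazine genes outside the operons.

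Between titles, libraries of the same named experiment paired in iron starvation, where the correlations of their deviations were 0.286 to 0.819, but not in heat shock at 50 °C (-0.164) or low osmolarity (-0.0718), and the experiment was an alternative block for the titles. Copied counts were looked for within groups: 0 of 70 pairs were identical, and their chi-square per degree of freedom was 2.20 to 45.4.

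The calculations were tested on simulated data drawn from the means and library sizes of the real libraries, with 200 genes changed. Of 100 genes changed 2-fold, 55% were called in the iron starvation comparison, 43% in transitional growth and 2% to 32% in the other comparisons of conditions, and 83% in the title comparison. Of 100 changed 4-fold, 34% (48 h against 24 h biofilm) to 96% (titles) were called. At most 8 of 5625 unchanged genes were called in the simulated data. There genes were drawn independently and each had the same spread in all groups, as the fit assumes. False calls from a spread that differs between groups were therefore not tested.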

Results

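The transcriptome of Pseudomonas aeruginosa PA14, an opportunistic pathogen, was recorded by RNA sequencing in 47 libraries, each made from RNA of 3 pooled cultures. The labels give 14 growth conditions of the wild type. Exponential growth (LB medium, 37 °C, OD600 1.0) and transitional growth (OD600 2.0) were represented by 5 libraries each, iron starvation by 8, low osmolarity and heat shock at 50 °C by 4 each, and each of the other 9 conditions by 2. Another 3 libraries carry titles that name an overexpressed sigma factor, 1 with RpoD in exponential growth and 2 with RpoN in transitional growth, and these were kept apart. Total counts ran from 427537 (anoxic replicate 1) to 8839347 (exponential growth replicate 1). Without ribosomal RNA (rRNA) the counts ran from 101008 (ex vivo tumor replicate 2) to 3104929 (exponential growth replicate 1). By total counts and TMM factor, 3 counts in a library corresponded to 0.232 CPM (transitional growth replicate 6) to 6.72 CPM (ex vivo tumor replicate 2). For a group at 0 counts, folds are given as at least the fold over 3 counts in that group. The rRNA share lay between 44.4% and 97.4% in 45 libraries and at 0.639% and 0.33% in the 2 anoxic libraries. The stable RNAs rnpB, ssrA and ssrS together took 24.8% and 27.0% of the anoxic counts, against 0.527% to 6.38% elsewhere. Levels are given as TMM-normalised CPM (mean ± SD, n libraries). Changes are given as log2 fold changes ± SE with Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test.

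**Figure D1:**
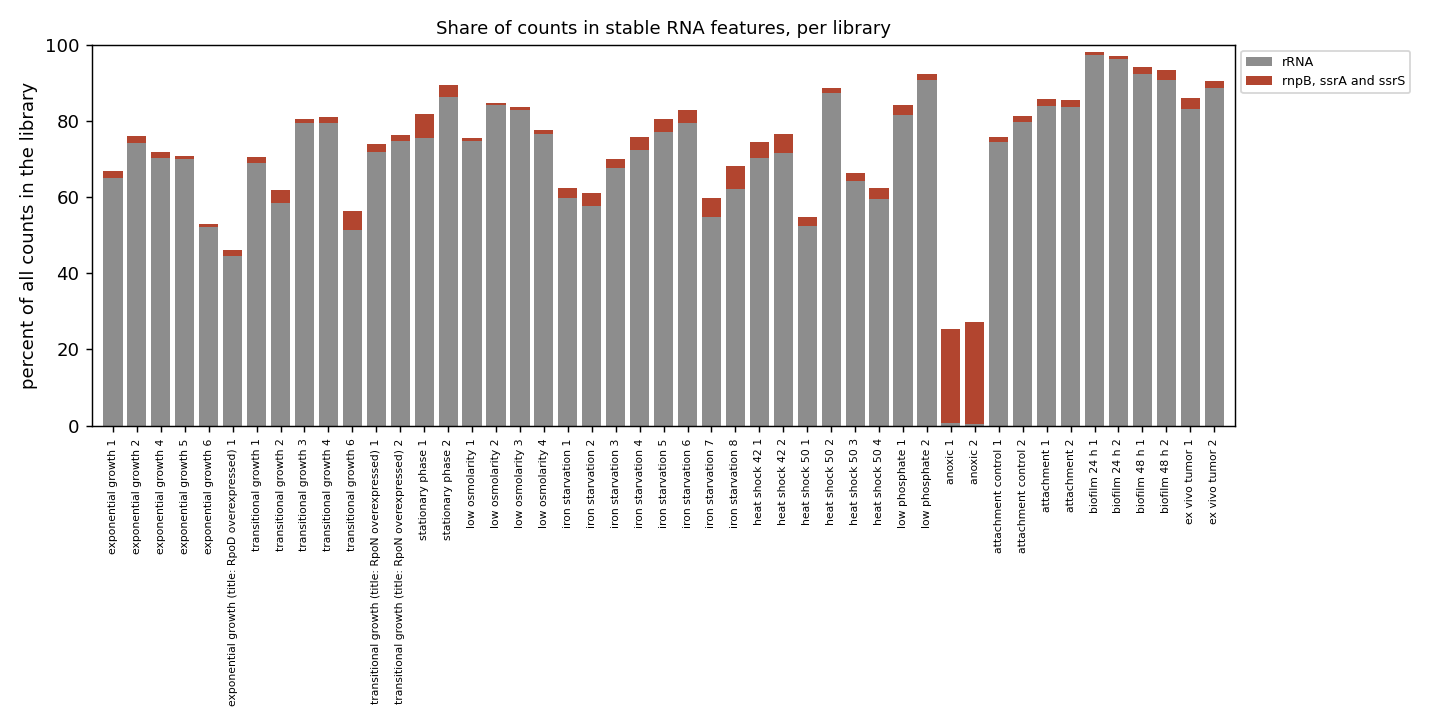
Percent of all counts in each of the 47 libraries (horizontal axis) that fell on rRNA features (grey) and on rnpB, ssrA and ssrS (red). The 2 anoxic libraries hold 0.639% and 0.33% rRNA, against 44.4% to 97.4% in the other 45.

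Nearly the whole transcriptome responded to the growth condition: 5593 of 5876 genes tested differed among the 14 conditions. Pairwise comparisons against the nearest reference condition called between 94 and 3659 genes, and the comparison of library titles called 46.

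**Figure D2:**
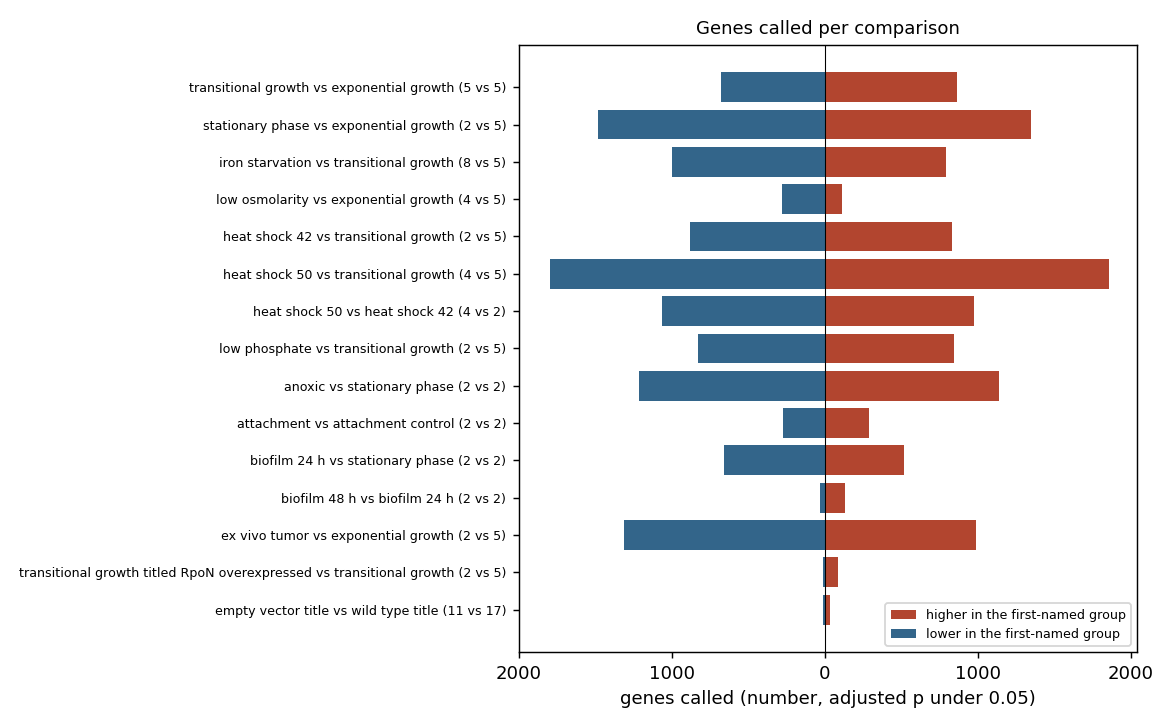
Number of genes called at an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis, with the number of libraries per group), higher in the first-named group to the right and lower to the left. Heat shock at 50 °C against transitional growth called 3659 genes, and the comparison of titles 46.

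The series recorded how the sigma factor network of the strain is used across conditions, and the sigma factor genes themselves differed widely between them. The gene rpoS, for the general stress and stationary phase sigma factor, was highest in stationary phase at 2975 ± 1100 CPM (n = 2). It was lowest after heat shock at 50 °C at 79.9 ± 18.7 CPM (n = 4), a ratio of 37.2 (adjusted p = 2.88e-16 across conditions). The heat shock sigma factor gene rpoH peaked at 50 °C with 1062 ± 341 CPM (n = 4), 11.1 times its level of 95.6 ± 27.1 CPM (n = 5) in transitional growth. The housekeeping gene rpoD was also highest at 50 °C, at 1354 ± 565 CPM, and lowest in the anoxic libraries at 155 ± 86.9 CPM (n = 2). Among the others, algU (envelope stress) ran from 169 ± 61.4 CPM in low osmolarity (n = 4) to 1125 ± 37.3 CPM in the tumor libraries (n = 2). The gene rpoN (nitrogen metabolism and motility) ran from 80.6 ± 3.12 CPM in the 24 h biofilm to 280 ± 22.0 CPM in the tumor libraries, and the envelope-related sigX from 269 ± 75.0 CPM in the anoxic libraries to 1358 ± 251 CPM after heat shock at 42 °C. The flagellar sigma factor gene fliA varied least of these, by a ratio of 3.00 between the anoxic libraries (151 ± 42.8 CPM, n = 2) and the 24 h biofilm (adjusted p = 0.00305). Genes of iron-responsive sigma factors were low in most conditions. The gene pvdS reached 36.9 ± 5.55 CPM in stationary phase and 25.2 ± 13.2 CPM (n = 8) in iron starvation and was at 0 counts in both attachment control libraries. The gene fiuI ran from 0.0650 ± 0.130 CPM in low osmolarity to 20.9 ± 1.37 CPM in stationary phase.

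**Figure D3:**
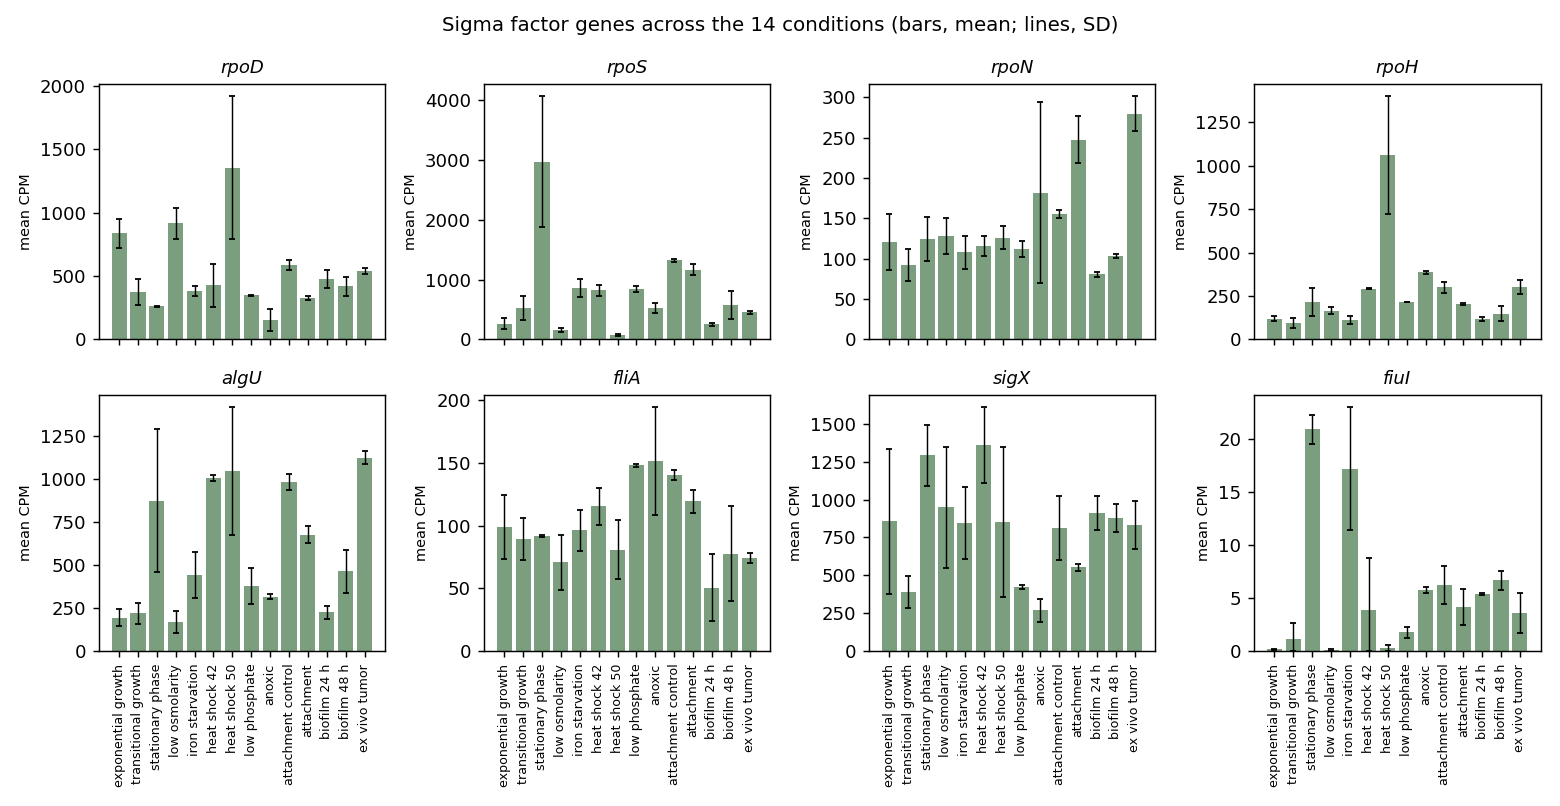
Mean CPM (vertical axes, starting at 0) of 8 sigma factor genes in the 14 conditions (horizontal axes); bars are means and lines are 1 SD over the libraries of a condition, drawn no lower than 0. The rpoS bar is highest in stationary phase (2975 CPM) and the rpoH bar at 50 °C (1062 CPM).

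Entry into the transitional phase was compared with exponential growth in the same medium. Most of the listed exoproduct, phenazine and stationary phase genes rose, while the ribosomal protein genes fell. The chitinase gene chiC rose by 3.73 ± 0.37 (67.7 ± 30.5 against 4.91 ± 2.86 CPM, n = 5 each) and the alkaline protease gene aprA by 3.13 ± 0.37. The elastase genes lasA and lasB rose by 3.03 ± 0.34 and 2.94 ± 0.36. Of 18 quorum-sensing controlled exoproduct genes, 14 were higher, 0 lower and 4 not called (14 and 0 adjusted over the list alone; camera adjusted p = 5.11e-11, and adjusted p = 0.0825 with an estimated correlation). Of 22 phenazine genes 18 were higher and 4 not called (19 higher adjusted over the list alone; adjusted p = 1.26e-15, and adjusted p = 0.066 with an estimated correlation). The largest changes were in mexI (3.35 ± 0.35), mexH (3.27 ± 0.43) and opmD (3.07 ± 0.38) of an efflux pump that exports phenazines. Of 12 stationary phase genes 11 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 2.58e-09, and adjusted p = 0.0825 with an estimated correlation). Among them katE, a catalase gene, rose by 3.91 ± 0.46, and the ribosome modulation factor gene rmf by 3.50 ± 0.43 (195 ± 129 against 17.1 ± 9.57 CPM). The glycogen genes glgP and glgA rose by 3.49 ± 0.37 and 3.34 ± 0.40. All 52 ribosomal protein genes were lower (52 adjusted over the list alone; adjusted p = 1.29e-31, and adjusted p = 0.168 with an estimated correlation), for example rplE by -2.02 ± 0.30 and rplX by -1.98 ± 0.32.

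In the same comparison the nitric oxide reductase accessory gene norD and the nitrous oxide reductase gene nosZ rose by 4.70 ± 0.55 and 4.14 ± 0.50. The nitrate transporter genes narK1 and narK2 fell by 2.80 and 2.01 on the log2 scale. The cytochrome oxidase gene ccoP (PA14_44360) changed by -2.15 ± 0.46. Of 15 quorum sensing regulator genes, rhlR was higher (0.86 ± 0.23), lasI lower (-0.82 ± 0.21) and 13 were not called (1 and 1 adjusted over the list alone; adjusted p = 0.917). In all, 1547 of 5876 genes were called, 868 higher and 679 lower. Transitional growth replicates 2 and 6 correlated with each other at r = 0.978 across genes, and with the other 3 transitional libraries at 0.901 to 0.932, while those 3 correlated with each other at 0.885 or more (0.952 between replicates 1 and 3). The calls fell to 520 (413 higher, 107 lower) with only those 2 kept, a choice made after seeing the data. CcoP, rplJ, rhlR and lasI then lost their calls (adjusted p = 0.146, 0.0558, 0.354 and 0.363).

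Stationary phase (12 h) extended several of these changes. The small RNA genes prrH and prrF1, which act in iron homeostasis, stood at 1160 ± 1147 and 9292 ± 9980 CPM (n = 2) against 0.607 ± 0.62 and 4.98 ± 5.23 CPM in exponential growth (n = 5), increases of 11.03 ± 0.85 and 10.94 ± 1.05. The prrF1 level was 16349 CPM in replicate 1 and 2236 CPM in replicate 2. The exoproduct genes chiC, lasA and lasB rose by 7.74 ± 0.46, 7.31 ± 0.43 and 6.22 ± 0.44, the last to 12040 ± 3144 CPM, and the lectin gene pa1L by 8.47 ± 0.66. Of the 18 exoproduct genes 12 were higher and 6 not called (12 higher adjusted over the list alone; adjusted p = 1.12e-08, and adjusted p = 0.138 with an estimated correlation). Of the 12 stationary phase genes 10 were higher, 1 lower and 1 not called (10 and 1 adjusted over the list alone; adjusted p = 1.56e-09, and adjusted p = 0.066 with an estimated correlation). Their member rmf stood at 2131 ± 804 CPM (6.95 ± 0.53). The aa3 oxidase genes coxA, coIII and coxB rose by 6.81 ± 0.47, 5.91 ± 0.36 and 5.63 ± 0.37. Among the lower genes were nirS, for nitrite reductase (-5.02 ± 0.83), ccpR, for a cytochrome c peroxidase (-5.61 ± 0.82), and ccoN (PA14_44340), for an oxidase subunit (-4.44 ± 0.69). For narK2 only 1 count was found in the 2 stationary libraries, and its CPM in exponential growth was 291 times higher (95% counting interval 52.1 to 11500).

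Quorum sensing regulator genes in stationary phase split, with 4 higher, 7 lower and 4 not called of 15 (4 and 7 adjusted over the list alone; adjusted p = 0.0694). The quinolone synthesis genes pqsD, pqsC, pqsB and pqsE were lower by -4.11 ± 0.42, -4.06 ± 0.48, -3.98 ± 0.39 and -3.92 ± 0.47. Phenazine genes also split (6 higher, 7 lower, 9 not called of 22, and 6 and 7 adjusted over the list alone; adjusted p = 0.369). The pump genes mexH and mexG rose by 4.54 ± 0.49 and 4.38 ± 0.47. Ribosomal protein genes were lower in 42 of 52 cases (44 adjusted over the list alone; adjusted p = 3.83e-07, and adjusted p = 0.601 with an estimated correlation), for example rplY by -2.60 ± 0.48, which was not called against transitional growth (-0.83, adjusted p = 0.136). Of 21 ATP synthase and NADH dehydrogenase genes 12 were lower, 1 higher and 8 not called (14 and 1 adjusted over the list alone; adjusted p = 0.00275, and adjusted p = 0.596 with an estimated correlation). The NADH dehydrogenase genes nuoK and nuoM changed by -1.95 ± 0.33 and -1.95 ± 0.35. Of 42 flagellum genes 12 were lower and 30 not called (7 lower adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.68 with an estimated correlation). With RLE factors in place of TMM the adjusted p of the list was 0.0545, and DESeq2 called 7 lower. The call of flgC (-1.62 ± 0.40) ended without stationary phase replicate 2 (adjusted p = 0.0913). In all 2830 genes were called, 1350 higher and 1480 lower. With RLE factors the split was 1634 and 1147, the median of all genes moving by 0.25 on the log2 scale.

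Iron starvation, imposed with the chelator 2,2'-bipyridyl for 70 min in 50% LB (OD600 1.5), was compared with transitional growth in LB (OD600 2.0). The medium and the OD600 thus differed as well as iron. Most genes of the 4 iron acquisition lists were higher. All 16 pyoverdine genes were higher (16 adjusted over the list alone; adjusted p = 1.27e-22, and adjusted p = 0.066 with an estimated correlation). The sigma factor gene pvdS rose by 7.07 ± 0.72 (25.2 ± 13.2 CPM, n = 8, against 0.237 ± 0.465 CPM, n = 5). The synthesis genes pvdQ, pvdA and pvdL rose by 6.93 ± 0.71, 6.14 ± 0.62 and 5.92 ± 0.58. All 11 pyochelin genes were higher (11 adjusted over the list alone; adjusted p = 1.95e-10, and adjusted p = 0.204 with an estimated correlation). The receptor gene fptA stood at 974 ± 301 against 65.4 ± 29.8 CPM. Of 9 heme uptake genes 7 were higher and 2 not called (8 higher adjusted over the list alone; adjusted p = 1.47e-08, and adjusted p = 0.132 with an estimated correlation). The hemophore gene hasAp rose by 5.16 ± 0.65 and phuS by 4.69 ± 0.37. Of 20 other iron-responsive genes 15 were higher, 1 lower and 4 not called (16 and 1 adjusted over the list alone; adjusted p = 2.90e-13, and adjusted p = 0.049 with an estimated correlation). The iron-free fumarase and superoxide dismutase genes fumC and sodM rose by 7.40 ± 0.54 and 6.46 ± 0.53, and the ferredoxin gene bfd by 4.85 ± 0.56.

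The small RNA gene prrF1 rose by 7.77 ± 0.90 to 3644 ± 4105 CPM, and prrF2 by 6.94 ± 0.82, in iron starvation. Of 11 iron storage and iron enzyme genes 6 were lower and 5 not called (7 lower adjusted over the list alone; adjusted p = 8.71e-04, and adjusted p = 0.215 with an estimated correlation). The bacterioferritin gene bfrB changed by -2.08 ± 0.30, the succinate dehydrogenase gene sdhC by -1.72 ± 0.34 and the iron superoxide dismutase gene sodB by -1.45 ± 0.33. The largest decreases were in denitrification, with norB at 2.14 ± 0.734 against 193 ± 225 CPM (-6.47 ± 0.57), nosZ by -6.11 ± 0.48 and nirS by -5.78 ± 0.46. In the transitional reference norB ran from 27.6 to 583 CPM between libraries, and nosZ was itself higher there than in exponential growth. Whether iron, OD600 or medium lowered these genes was not tested. Altogether 1791 genes were called, 794 higher and 997 lower. Without transitional growth replicates 2 and 6, a choice made after seeing the data, 928 were called and bfrA (-1.28 ± 0.26) lost its call (adjusted p = 0.169). Against exponential growth instead, 3298 were called and phzS, lower here by -1.85 ± 0.37, lay at 0.07.

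Low osmolarity (LB with 8 mM NaCl, OD600 1.0) against exponential growth changed fewer genes. The oprH-phoP-phoQ operon, which encodes an outer membrane protein and a magnesium-responsive regulatory pair, fell. The outer membrane protein gene oprH changed by -3.28 ± 0.34 (7.82 ± 2.83 CPM, n = 4, against 77.4 ± 14.2 CPM, n = 5), phoQ by -2.59 ± 0.31 and phoP by -2.50 ± 0.32. Of 17 osmoadaptation genes 5 were lower and 12 not called (7 lower adjusted over the list alone; adjusted p = 5.37e-07, and adjusted p = 0.0086 with an estimated correlation). BetA and betB, which make the compatible solute glycine betaine, changed by -2.25 ± 0.32 and -2.20 ± 0.33, the choline transporter gene betT by -1.73 ± 0.29 and osmC by -2.57 ± 0.57. The malate:quinone oxidoreductase gene mqoA (1.72 ± 0.27) and the thioredoxin gene trxA (PA14_69200) (1.19 ± 0.21) rose. The sulfate assimilation genes sbp (2.40 ± 0.52) and cysD (2.10 ± 0.45) lost their calls without low osmolarity replicate 3 (adjusted p = 0.222 and 0.0892) and without the libraries titled empty vector (adjusted p = 0.289 and 0.149). Of 13 fatty acid synthesis genes fabF1 was higher (0.74 ± 0.21), fabI lower (-0.72 ± 0.21) and 11 were not called (2 and 1 adjusted over the list alone; adjusted p = 0.00523, and adjusted p = 0.38 with an estimated correlation). Both calls ended when low osmolarity replicate 3 or certain other libraries were left out (adjusted p = 0.0761 and 0.16 without replicate 3), and the fabI call also with RLE and upper quartile factors (adjusted p = 0.0922 and 0.092). Of 11 AlgU envelope stress genes osmC and algR (-0.95 ± 0.24) were lower and 9 not called (3 lower adjusted over the list alone; adjusted p = 0.067).

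In low osmolarity 393 genes were called, 111 higher and 282 lower. With RLE factors the split was 188 and 191 and with upper quartile factors 177 and 194, the median of all genes moving by 0.11 on the log2 scale with either. The count fell to 195 without low osmolarity replicate 3 and to 240 without its replicate 1, both titled empty vector. It fell to 236 and 234 without exponential growth replicates 1 and 2, both titled wild type. It was 68 with only the libraries whose titles name no empty vector, where algR, fabF1 and fabI also lost their calls (adjusted p = 0.197, 0.284 and 0.49).

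Heat shock at 42 °C, after growth in LB to OD600 2.2 for a duration the labels do not state, was compared with transitional growth. Most of the listed heat shock genes were higher but varied between the 2 libraries. The small heat shock protein gene ibpA rose by 4.97 ± 0.70, at 1279 CPM in replicate 1 and 386 CPM in replicate 2, against 24.6 ± 45.3 CPM (n = 5). Of 18 heat shock genes 13 were higher and 5 not called (13 adjusted over the list alone; adjusted p = 9.75e-07, and adjusted p = 0.317 with an estimated correlation). GrpE, htpG and dnaK rose by 3.13 ± 0.63, 2.85 ± 0.67 and 2.70 ± 0.66, and these 3 calls ended without heat shock replicate 1 (adjusted p = 0.127, 0.342 and 0.379). They also ended against exponential growth, where the 3 genes lay at 1.20, 0.69 and 0.55 (adjusted p = 0.123, 0.442 and 0.546), and with the libraries of these 2 groups alone (adjusted p = 0.055, 0.105 and 0.108). Among the transitional libraries replicate 2 also held high levels of these genes, with dnaK at 935 CPM against at most 88.1 CPM in the other 4. It exceeded heat shock replicate 2 in dnaK (508 CPM there), htpG (706 against 398 CPM) and grpE (98.7 against 85.8 CPM). It did not in ibpA (106 against 386 CPM). Transitional growth replicate 2 and heat shock replicate 1 are the only libraries of their groups titled empty vector. The kind of title and a deviation of these libraries cannot be told apart here. Of 11 AlgU envelope stress genes 6 were higher, mucD was lower and 4 were not called (7 and 1 adjusted over the list alone; adjusted p = 0.00898, and adjusted p = 0.462 with an estimated correlation). The mucD call ended without heat shock replicate 2 and with the libraries of these 2 groups alone (adjusted p = 0.105 and 0.0595). AlgU and mucA, which encodes its anti-sigma factor, rose by 2.19 ± 0.33 and 1.93 ± 0.30. The oxidase genes coxA and coxB rose by 4.32 ± 0.43 and 4.30 ± 0.36, and the small RNA genes prrF1 and rgsA by 4.90 ± 0.89 and 4.12 ± 0.82. The phenazine gene phzS (-3.27 ± 0.68), the export chaperone gene secB (-2.67 ± 0.40) and the pyrophosphatase gene ppa (-2.58 ± 0.50) fell. Against exponential growth phzS was not called (-1.35, adjusted p = 0.0666).

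After the 42 °C shock 1717 genes were called, 833 higher and 884 lower. The count was 950 and 1038 without heat shock replicates 1 and 2, 894 without the libraries titled empty vector, and 947 with the libraries of these 2 groups alone. It was 2664 against exponential growth, and 1100 without transitional growth replicates 2 and 6, a choice made after seeing the data.

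Heat shock at 50 °C gave the largest number of called genes. The chaperone genes dnaK, htpG and grpE reached 6395 ± 735, 4189 ± 1478 and 915 ± 334 CPM (n = 4), increases of 4.77 ± 0.63, 4.60 ± 0.64 and 5.11 ± 0.61 over transitional growth (n = 5). The gene ibpA rose by 5.74 ± 0.67. Of 18 heat shock genes 14 were higher, 1 lower and 3 not called (14 and 1 adjusted over the list alone; adjusted p = 4.21e-07, and adjusted p = 0.277 with an estimated correlation). Of 13 alginate synthesis genes, which make a capsular exopolysaccharide, 11 were higher and 2 not called (12 higher adjusted over the list alone; adjusted p = 0.00344, and adjusted p = 0.277 with an estimated correlation). Levels were low, with algD at 13.3 ± 5.51 against 0.791 ± 0.694 CPM. Of 11 AlgU envelope stress genes 7 were higher, 2 lower and 2 not called (7 and 2 adjusted over the list alone; adjusted p = 0.0537). With RLE and upper quartile factors the list was called (adjusted p = 0.0306 and 0.0354), but not with an estimated correlation (adjusted p = 0.596). The genes mucA and algU rose by 2.76 ± 0.26 and 2.25 ± 0.29. The oxidase genes coxA, coxB and coIII rose by 5.54 ± 0.41, 5.35 ± 0.34 and 4.88 ± 0.33. Glucose transport genes gltF and gltB (PA14_22980) changed by -5.64 ± 0.71 and -5.42 ± 0.45. The coenzyme A transferase genes scoB and scoA changed by -5.03 ± 0.44 and -4.71 ± 0.35, and the autoinducer synthase gene rhlI by -4.44 ± 0.31. Of 52 ribosomal protein genes 26 were lower and 26 not called (21 lower adjusted over the list alone; adjusted p = 0.0211, and adjusted p = 0.867 with an estimated correlation). The gene rpsA changed by -2.30 ± 0.34. In all 3659 genes were called, 1861 higher and 1798 lower, and with RLE and upper quartile factors the median of all genes moved by 0.26 and 0.14.

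Between the 2 temperatures, 50 °C against 42 °C, 2036 genes were called, 973 higher and 1063 lower (1273 and 905 with RLE factors, the median of all genes moving by 0.18, and by 0.16 with upper quartile factors). Of 18 heat shock genes 8 were higher at 50 °C, 1 lower and 9 not called (10 and 1 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.596 with an estimated correlation). The sigma factor gene rpoH was higher by 1.86 ± 0.31 (1062 ± 341 against 294 ± 4.97 CPM). The chaperone genes dnaK (2.08 ± 0.81), grpE and dnaJ lost their calls without heat shock 42 replicate 2 (adjusted p = 0.363, 0.36 and 0.415). DnaK and dnaJ also lost them with the libraries of these 2 groups alone (adjusted p = 0.054 and 0.0653), and all 3 without heat shock 50 replicate 4 (adjusted p = 0.0643, 0.0668 and 0.082). The topoisomerase gene topA (2.72 ± 0.40), the glutathione synthesis gene gshA (3.12 ± 0.35) and lpd3 (3.21 ± 0.43) were also higher at 50 °C. Lower were scoA (-5.37 ± 0.39), rhlI (-4.88 ± 0.34), the tyrosine catabolism gene hpd (-4.57 ± 0.41), nirS (-4.55 ± 0.63) and the oxygen-independent heme synthesis gene hemN (-3.81 ± 0.45). Of 13 alginate genes 7 were higher and 6 not called (7 adjusted over the list alone; adjusted p = 0.00352, and adjusted p = 0.204 with an estimated correlation). AlgX, with 2 counts at 42 °C, was higher by a ratio of 10.3 (95% counting interval 2.73 to 86.6). Of 11 AlgU envelope stress genes mucD was higher (0.85 ± 0.28), algW lower (-0.91 ± 0.32) and 9 not called (1 and 1 adjusted over the list alone; adjusted p = 0.688). The mucD and algW calls ended without heat shock 42 replicate 2 (adjusted p = 0.278 and 0.345) and with the libraries of these 2 groups alone (adjusted p = 0.16 and 0.112). The algW call also ended with RLE factors, upper quartile factors and DESeq2 (adjusted p = 0.07, 0.0562 and 0.0516). The count of called genes was 1049 without heat shock 42 replicate 2 and 1131 with the libraries of these 2 groups alone.

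Growth in low phosphate (DeMoss medium, OD600 2.0) was compared with transitional growth in LB, so the medium differed as well as phosphate. Phosphate acquisition genes showed the largest increases. The phosphonate transport genes phnD, phnE and phnC rose to 1412 ± 155, 599 ± 115 and 536 ± 32.9 CPM (n = 2) from 0.869 ± 0.556, 1.13 ± 0.901 and 0.709 ± 0.456 CPM (n = 5). These were increases of 10.49 ± 0.44, 9.33 ± 0.44 and 9.24 ± 0.47. The polyphosphate porin gene oprO rose by 9.07 ± 0.39, the alkaline phosphatase gene phoA by 8.48 ± 0.53 and the phospholipase gene plcN by 7.38 ± 0.42. Of 29 phosphate starvation genes 27 were higher and 2 not called (27 adjusted over the list alone; adjusted p = 1.27e-75, and adjusted p = 2.35e-09 with an estimated correlation). The methionine synthase gene metE (4.95 ± 0.52) and leuA, for leucine synthesis (2.38 ± 0.22), rose. Of 57 amino acid synthesis genes 4 were higher, 10 lower and 43 not called (4 and 9 adjusted over the list alone; adjusted p = 0.687). The rhamnolipid genes rhlB and rhlA rose by 3.01 ± 0.36 and 2.67 ± 0.40. The protease gene aprA and aprD changed by -2.87 ± 0.54 and -2.30 ± 0.47. Of the 18 exoproduct genes 4 were higher, 8 lower and 6 not called (4 and 8 adjusted over the list alone; adjusted p = 0.606).

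Of 4 type VI secretion genes measured, hcpC (2.79 ± 0.59), hcpB (2.21 ± 0.51) and hcpA (2.10 ± 0.56) were higher in low phosphate and 1 not called (3 adjusted over the list alone; adjusted p = 0.233). HcpC lost its call without low phosphate replicate 2 (adjusted p = 0.0961). HcpB and hcpA lost theirs with the libraries titled overexpressed merged into their conditions (1.23 and 1.21, adjusted p = 0.0775 and 0.099), and hcpA also without transitional growth replicates 2 and 6 (adjusted p = 0.0818). The genes bkdB and lpdV, for catabolism of branched-chain amino acids, changed by -6.71 ± 0.55 and -6.06 ± 0.61. The nitric oxide reductase gene norC had 0 counts in both low phosphate libraries and was at least 92.1-fold lower than in transitional growth. In all 1676 genes were called, 844 higher and 832 lower, and with RLE factors the median of all genes moved by 0.17. The count was 913 and 1069 without low phosphate replicates 1 and 2 and 2523 against exponential growth, where aprA lay at 0.26 and aprD was not called (-1.05, adjusted p = 0.0569).

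**Figure D4:**
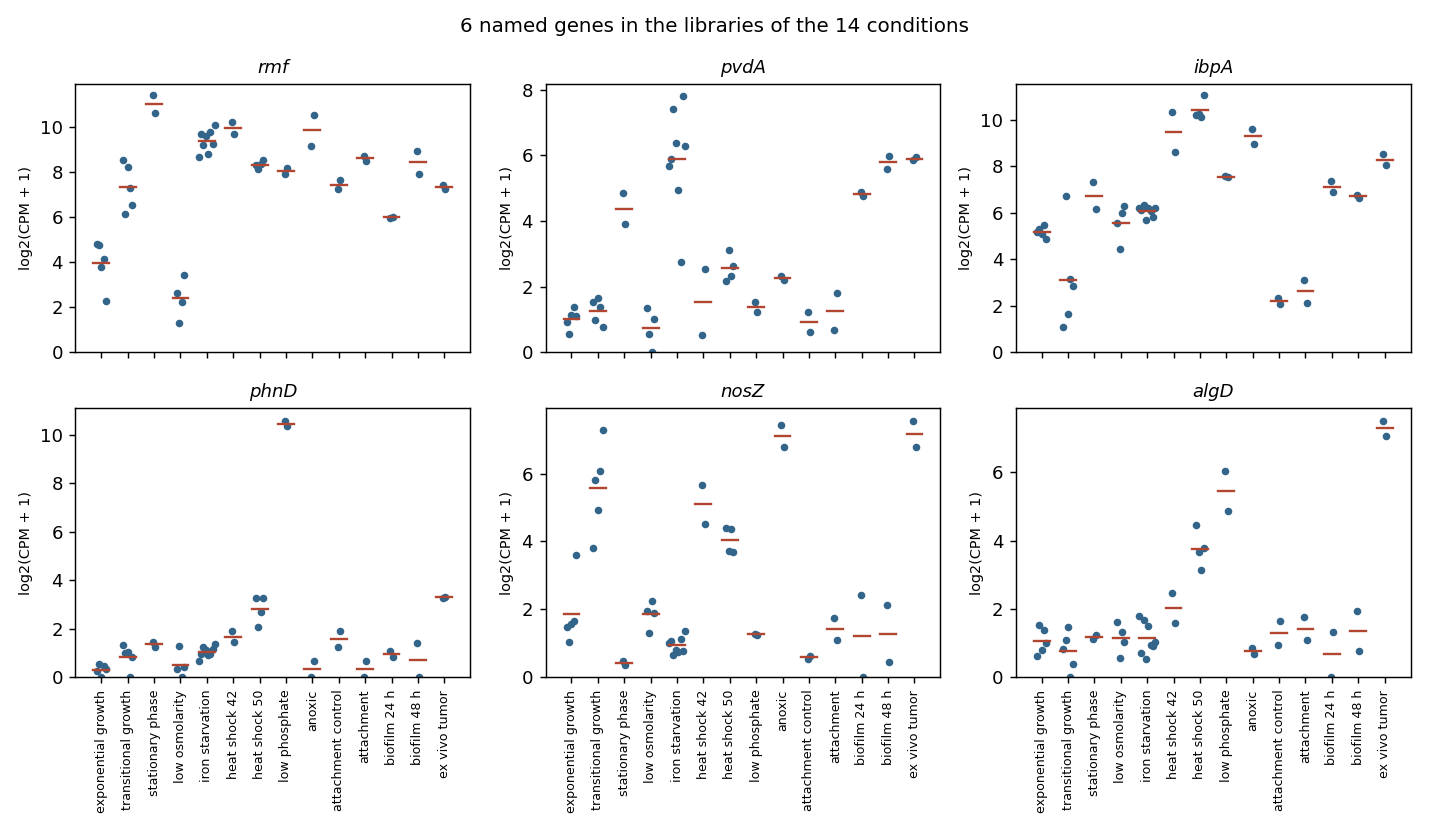
Level of 6 named genes as log2(CPM + 1) (vertical axes) in every library of the 14 conditions (horizontal axes); points are libraries and red lines the mean of the points. The phnD points of low phosphate (mean 1412 CPM) and the ibpA points of heat shock at 50 °C (mean 1415 CPM) lie above those of transitional growth (means 0.869 and 24.6 CPM).

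Anaerobic growth for 16 h with 100 mM KNO3 was compared with stationary phase, in another medium. Most of the listed denitrification genes were higher. The gene norD stood at 523 ± 254 against 0.565 ± 0.0239 CPM (n = 2 each, 9.78 ± 1.12). The gene nirM, for an electron donor of nitrite reductase, stood at 457 ± 274 against 0.781 ± 0.831 CPM (9.29 ± 0.97), and nirF, for heme d1 synthesis, rose by 7.97 ± 1.03. The stationary libraries held only 3 counts each of nosR and nosZ. The anoxic CPM was 1230 times (95% counting interval 419 to 5960) and 400 times (136 to 1950) higher. These folds hold against stationary phase only. The anoxic mean of nosZ was 141 CPM, and the transitional growth libraries ran from 12.9 to 156 CPM. For norD the transitional mean was 49.6 CPM, below its anoxic level. Of 35 denitrification genes 28 were higher, 3 lower and 4 not called (28 and 3 adjusted over the list alone; adjusted p = 1.95e-10, and adjusted p = 0.168 with an estimated correlation). Of 15 other low-oxygen genes 7 were higher, 5 lower and 3 not called (7 and 5 adjusted over the list alone; adjusted p = 0.501). The anaerobic ribonucleotide reductase gene nrdD rose by 4.95 ± 0.87 (1.11 against exponential growth, not called, adjusted p = 0.0819) and the acetate kinase gene ackA by 3.72 ± 0.48, while arcB, of arginine fermentation, changed by -2.47 ± 0.49. Of 22 tricarboxylic acid and glyoxylate cycle genes 8 were lower, 2 higher and 12 not called (9 and 2 adjusted over the list alone; adjusted p = 0.0239, and adjusted p = 0.614 with an estimated correlation). The genes lpdG, sucC and sucD changed by -3.47 ± 0.37, -3.42 ± 0.38 and -3.22 ± 0.41. The pyochelin genes pchI and pchC held 1 anoxic count each, and their stationary CPM was 680 times (122 to 26900) and 629 times (113 to 24900) higher. Against exponential growth pchC was not called (adjusted p = 0.0573).

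Of 22 phenazine genes 20 were lower, 1 higher and 1 not called in the anoxic libraries (20 and 1 adjusted over the list alone; adjusted p = 1.36e-07, and adjusted p = 0.204 with an estimated correlation). Of these, 14 belong to the near-identical operons phz1 and phz2. PhzE1 and phzA1, for example, had 0 anoxic counts and were at least 37.2-fold and 35.4-fold lower. Of the 8 members outside the operons 6 were lower and 1 higher. In the same libraries 8 of 12 rRNA features were at 0 counts. The ratio of the near-identical elongation factor genes tufA and tufB to fusA1 was 0.0679 and 0.104, against 0.583 to 1.92 in the other 45 libraries. The levels of features with close copies are therefore uncertain here. In all 2352 genes were called, 1140 higher and 1212 lower, and with RLE factors the median of all genes moved by 0.27.

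Attachment, in which cells were held for 1 h on a harvesting device, was compared with agitated cells in the same M9 medium. The strongest increases were in the copper resistance genes pcoA (791 ± 7.43 against 2.28 ± 1.32 CPM, n = 2 each, 8.46 ± 0.48) and pcoB (267 ± 28.1 against 0.942 ± 0.574 CPM, 8.06 ± 0.65). Other increases were in the tRNA modification gene queF (5.88 ± 0.48), the polyamine catabolism gene pauA (5.90 ± 0.49), the porin gene oprD3 (4.09 ± 0.40) and the lipase gene lipA (4.03 ± 0.57). Lower were malQ (-4.02 ± 0.71) and glgX (-3.20 ± 0.67), for glycogen use, katE (-3.83 ± 0.67), the aquaporin gene aqpZ (-3.42 ± 0.48) and lasB (-2.84 ± 0.57). Of 29 type IV pilus genes 5 were higher and 24 not called (5 adjusted over the list alone; adjusted p = 6.21e-04, and adjusted p = 0.43 with an estimated correlation). The minor pilin genes fimU and pilX rose by 2.03 ± 0.39 and 1.91 ± 0.39 and the adhesin gene pilY1 by 1.91 ± 0.37. Of 42 flagellum genes 12 were lower and 30 not called (16 lower adjusted over the list alone; adjusted p = 8.71e-08, and adjusted p = 0.272 with an estimated correlation). Lower genes included fleR (-2.12 ± 0.32), flgH (-1.74 ± 0.31) and fleS (-1.69 ± 0.37). Of 7 chemotaxis genes pctC was higher (1.14 ± 0.37) and 6 not called (1 adjusted over the list alone; adjusted p = 0.98). The pctC call ended when any of the 4 libraries was left out (adjusted p = 0.0859 to 0.209).

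Of 6 surface attachment genes, pilY1 was higher and 5 not called (1 adjusted over the list alone; adjusted p = 0.558). Among 17 biofilm matrix and cyclic di-GMP genes 0 were called with edgeR, 0 with DESeq2 and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone; adjusted p = 0.51). With these group sizes 6% of 2-fold and 38% of 4-fold changes were called in simulated data, so most differences of that size would be missed. In all 562 genes were called, 287 higher and 275 lower. The count was 290, 271, 241 and 305 without attachment replicates 1 and 2 and control replicates 1 and 2, and 1599 with the spread estimated from these 4 libraries alone.

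Biofilms of 24 h in 96-well plates were compared with planktonic stationary phase. The small RNA genes prrH (-5.63 ± 1.01) and prrF1 (-5.63 ± 1.28) were lower in the biofilm. So were rmf (62.5 ± 2.06 against 2131 ± 804 CPM, n = 2 each, -5.09 ± 0.74) and lasB (-4.18 ± 0.60). The amidase gene amiE (-4.02 ± 0.40) and amiR (-3.87 ± 0.56) were also lower. The prrF1 call ended without stationary phase replicate 1 and without biofilm replicate 2 (adjusted p = 0.066 and 0.056). Higher were the glycine cleavage gene gcvP2 (98.0 ± 4.55 against 7.84 ± 4.79 CPM, 3.66 ± 0.48), ccpR (3.71 ± 0.84), phzS (3.50 ± 0.75) and the purine synthesis gene purH (3.31 ± 0.53). Of 39 type III secretion genes 9 were lower and 30 not called (9 adjusted over the list alone; adjusted p = 0.067, 0.046 with upper quartile factors, and 0.79 with TMM factors and an estimated correlation). The gene exsB and the effector chaperone gene spcU changed by -3.58 ± 0.64 and -2.47 ± 0.39. Of 42 flagellum genes 6 were lower and 36 not called (5 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.692 with an estimated correlation). Of 17 biofilm matrix and cyclic di-GMP genes pelB and pelF (2.40 ± 0.66 and 2.30 ± 0.74, for an exopolysaccharide) were higher, wspB was lower (-1.34 ± 0.43) and 14 were not called (2 and 2 adjusted over the list alone; adjusted p = 0.874). These 3 calls ended without biofilm replicate 2 (adjusted p = 0.101, 0.15 and 0.121) and without stationary phase replicate 1 (adjusted p = 0.117, 0.169 and 0.0767).

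In the 24 h biofilm denitrification genes were mostly not called, with 2 of 35 higher, 3 lower and 30 not called (2 and 3 adjusted over the list alone; adjusted p = 0.0936). The lower ones were the periplasmic nitrate reductase genes napE (-3.71 ± 0.64), napD and napF. The napD call ended without biofilm replicate 1 (adjusted p = 0.157), and the napF call without biofilm replicate 2 and without stationary phase replicate 2 (adjusted p = 0.274 and 0.0632). Against exponential growth none of the 3 was called (adjusted p = 0.774, 0.728 and 0.767). Of 15 other low-oxygen genes 0 were called with edgeR (0 adjusted over the list alone, 5 at an unadjusted p under 0.05; adjusted p = 0.233), while DESeq2 called 2 higher. Of 29 type IV pilus genes 4 were higher, 3 lower and 22 not called (4 and 3 adjusted over the list alone; adjusted p = 0.502). In all 1172 genes were called, 516 higher and 656 lower, but 661 and 544 with upper quartile factors, the median of all genes moving by 0.15, and by 0.10 with RLE factors. The count was 690 and 540 without biofilm replicates 1 and 2 and 554 without stationary phase replicate 1, and against exponential growth rmf, lasB, prrH and prrF1 were higher rather than lower (1.86, 2.04, 5.40 and 5.31). CcpR was then lower rather than higher (-1.90, adjusted p = 0.0398), and gcvP2, phzS and purH were not called (0.55, 0.29 and -0.30, adjusted p = 0.302, 0.774 and 0.665). Also not called against exponential growth were amiE and amiR (-0.02 and 0.29, adjusted p = 0.983 and 0.773) and pelB and pelF (1.39 and 1.20, adjusted p = 0.0566 and 0.16).

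Between 24 h and 48 h of biofilm growth 160 genes were called, 131 higher and 29 lower at 48 h. With these group sizes 4% of 2-fold and 34% of 4-fold changes were called in simulated data, so most differences of that size would be missed. The small RNA genes rgsA (2372 ± 2798 against 15.5 ± 8.95 CPM, n = 2 each, 7.30 ± 1.25), rsmY (6830 ± 5310 against 628 ± 445 CPM, 3.44 ± 0.85), rsmZ (3.65 ± 0.91) and prrH (4.13 ± 0.95) were higher at 48 h. The gene rgsA stood at 4350 CPM in replicate 1 and 394 CPM in replicate 2, and rsmZ at 4194 and 469 CPM. The hemophore gene hasAp (3.64 ± 0.85) and the lectin gene pa1L (3.52 ± 0.78) were also higher. Lower at 48 h were the flagellin gene fliC (125 ± 29.1 against 398 ± 40.8 CPM, -1.67 ± 0.35), the arginine deiminase operon genes arcA and arcB (-1.74 ± 0.49 and -1.61 ± 0.46) and the ribosomal protein gene rplX (-1.84 ± 0.50). Of 35 denitrification genes napE and narL were higher (2.92 ± 0.65 and 1.41 ± 0.37) and 33 not called (2 adjusted over the list alone; adjusted p = 0.845). With edgeR 0 of 18 exoproduct genes (adjusted p = 0.935), 0 of 17 biofilm matrix and cyclic di-GMP genes (adjusted p = 0.22) and 0 of 11 SOS and pyocin genes (adjusted p = 0.874) were called, with 0 in each adjusted over the list alone. At an unadjusted p under 0.05 these lists had 3, 2 and 1 members, and DESeq2 called 1, 0 and 0. With upper quartile factors the split was 120 and 53, the median of all genes moving by -0.11. The count was 25 and 6 without 24 h replicates 1 and 2 and 40 and 68 without 48 h replicates 1 and 2, against 284 with DESeq2 and 418 with the libraries of these 2 groups alone. Against stationary phase it was 772, and rsmY, rsmZ, prrH and pa1L were not called there (0.60, 0.61, -1.50 and -0.09), nor were arcA, rplX and napE (-0.84, -0.10 and -0.78, adjusted p = 0.267, 0.927 and 0.313). Without 48 h replicate 1 all of the genes named here except rgsA lost their calls, rsmY, rsmZ and prrH falling to 2.19, 1.23 and 1.53 (adjusted p = 0.288, 0.631 and 0.514). Without 24 h replicate 1 all except rgsA and fliC lost them. Without 24 h replicate 2 all of the genes named here lost their calls (adjusted p = 0.0738 for rgsA and 0.0613 for fliC).

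Bacteria recovered from subcutaneous tumors of mice, where they had accumulated after intravenous injection, were compared with exponential growth in LB. Most genes of the pyoverdine, heme uptake and zinc limitation lists rose. Of 16 pyoverdine genes 15 were higher and 1 not called (15 adjusted over the list alone; adjusted p = 3.46e-11, and adjusted p = 0.189 with an estimated correlation). The receptor gene fpvA stood at 260 ± 19.2 CPM (n = 2) against 2.14 ± 0.608 CPM (n = 5, 6.93 ± 0.48). Of 9 heme uptake genes 6 were higher and 3 not called (6 adjusted over the list alone; adjusted p = 1.64e-06, and adjusted p = 0.189 with an estimated correlation). HasAp rose by 8.55 ± 0.67 and its receptor gene hasR by 6.65 ± 0.47. Of 11 pyochelin genes 4 were higher and 7 not called (4 adjusted over the list alone; adjusted p = 0.00836, and adjusted p = 0.64 with an estimated correlation). The synthesis gene pchE stood at 659 ± 157 against 25.8 ± 16.3 CPM. FptA, pchR and pchD lost their calls without tumor replicate 1 (adjusted p = 0.0903, 0.238 and 0.189). Of 6 zinc limitation genes 5 were higher and 1 not called (5 adjusted over the list alone; adjusted p = 1.08e-04, and adjusted p = 0.0738 with an estimated correlation). Among them were rpmE2, for a zinc-free ribosomal protein (6.37 ± 0.48), amiA (5.61 ± 0.58) and the zinc uptake regulator gene np20 (2.50 ± 0.40). Of 39 type III secretion genes 14 were higher and 25 not called (14 adjusted over the list alone; adjusted p = 5.38e-04, and adjusted p = 0.555 with an estimated correlation). The cytotoxin gene exoU stood at 1196 ± 94.9 against 140 ± 46.1 CPM (3.09 ± 0.29), the needle tip gene pcrV rose by 3.00 ± 0.36 and the translocator gene popB by 2.60 ± 0.36. The alginate gene algD stood at 158 ± 33.1 CPM, higher by 7.08 ± 0.45.

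Flagellum genes were lower in the tumor libraries in 26 of 42 cases, 1 was higher and 15 were not called (26 and 1 adjusted over the list alone; adjusted p = 3.07e-04, and adjusted p = 0.495 with an estimated correlation). The gene flgI changed by -2.25 ± 0.47, and DESeq2 called 15 flagellum genes lower. Of 35 denitrification genes 11 were higher, 3 lower and 21 not called (12 and 3 adjusted over the list alone; adjusted p = 0.0217, and adjusted p = 0.655 with an estimated correlation). The gene nosZ stood at 148 ± 54.9 against 3.60 ± 4.23 CPM. Of 17 sulfate limitation genes 3 were higher, 2 lower and 12 not called (3 and 2 adjusted over the list alone; adjusted p = 0.941), ssuD rising by 5.07 ± 1.26. The glucose transport gene gltK had 0 tumor counts and was at least 31.1-fold lower, the cyanide synthesis gene hcnC changed by -4.61 ± 0.58. The quinolone synthesis gene phnB, with 1 tumor count, was 103 times higher in exponential growth (95% counting interval 18.5 to 4080). The secretion gene pscP (843 ± 54.9 against 2.38 ± 1.32 CPM), the exopolysaccharide gene pelF (1230 ± 854 against 2.60 ± 1.16 CPM) and ykgJ (279 ± 96.5 against 0.569 ± 0.475 CPM) rose by 8.48 ± 0.40, 8.91 ± 0.42 and 8.82 ± 0.48. The median change of 12 neighbouring pel and psc genes was 0.76. Reads of mouse RNA counted at pscP, pelF and ykgJ were not excluded. In all 2298 genes were called, 987 higher and 1311 lower. With RLE and upper quartile factors the split was 1281 and 809, and 1170 and 973, the median of all genes moving by 0.46 and 0.30. The count was 1353 without tumor replicate 1, and against stationary phase fptA and pchD were lower rather than higher (-2.67 and -3.40, adjusted p = 0.0292 and 0.00844). Against stationary phase pvdS (6.02 ± 0.92 here), pchE and pchR were not called (-1.07, -0.19 and -1.20, adjusted p = 0.3, 0.9 and 0.138), nor were flgI, ssuD and gltK (-1.08, 2.05 and -7.94, adjusted p = 0.123, 0.223 and 0.0749).

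Titles of 3 libraries name an overexpressed sigma factor although the labels describe the wild type. In the library titled RpoD overexpressed, rpoD stood at 585 CPM, against 836 ± 112 CPM (n = 5, 683 to 949) in the other exponential libraries. In the libraries titled RpoN overexpressed, rpoN stood at 104 and 110 CPM, against 92.0 ± 19.7 CPM (n = 5, 63.4 to 111) in transitional growth. The titled overexpression was thus not seen in the level of either gene, and directions drawn from these libraries refer to the titles only. Against transitional growth the 2 libraries titled RpoN overexpressed had higher levels of the sigma factor gene sigX (1385 ± 783 against 390 ± 104 CPM, 1.83 ± 0.42) and the global repressor gene mvaT (794 ± 56.3 against 201 ± 116 CPM, 1.99 ± 0.41). Also higher were the thioredoxin reductase gene trxB2 (2.52 ± 0.62), the cold shock gene cspB (1.93 ± 0.41) and the pyocin immunity gene pyoS3I (1.93 ± 0.45), and the protease gene hslU was lower (-3.27 ± 0.82). Of 9 sigma factor genes sigX was higher and 8 not called (1 adjusted over the list alone; adjusted p = 0.0695). With edgeR 0 of 42 flagellum genes (adjusted p = 0.00664, lower as a set, and adjusted p = 0.614 with an estimated correlation) and 0 of 29 type IV pilus genes (adjusted p = 0.737) were called, with 0 in each adjusted over the list alone. At an unadjusted p under 0.05 these lists had 6 and 4 members, and DESeq2 called 1 and 0. In all 94 genes were called, 85 higher and 9 lower (65 and 17 with upper quartile factors). The count was 15 and 16 without the titled replicates 1 and 2 and 42 without transitional growth replicate 2, where hslU also lost its call (-1.20, adjusted p = 0.399). That replicate, titled empty vector, held hslU at 131 CPM, against 4.96 to 17.4 CPM in the other 4. With the libraries of these 2 groups alone none of the 6 genes named here was called (adjusted p = 0.0693 for sigX to 0.434 for hslU). Without titled replicate 2 the sigX and cspB calls ended (adjusted p = 0.594 and 0.237), as did those of mvaT, trxB2 and pyoS3I (adjusted p = 0.0587, 0.145 and 0.138).

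Other titles name an empty vector or a wild type of the same experiment. With the growth condition in the model, 11 libraries titled empty vector and 17 titled wild type differed in 46 of 5475 genes, 35 higher and 11 lower in the empty vector titles. With the experiment named in the titles added as a block the count was 56, 31 higher and 25 lower. The sulfate uptake gene cysP was higher (55.6 ± 47.6, n = 11, against 29.8 ± 12.8 CPM, n = 17, 0.81 ± 0.15), but was not called in iron starvation, heat shock 50 or low osmolarity alone (adjusted p = 0.0926, 0.766 and 0.13). The other 16 sulfate limitation genes were not called (1 adjusted over the list alone; adjusted p = 3.08e-04, and adjusted p = 0.468 with an estimated correlation). With edgeR 0 of 7 multidrug efflux genes (0 adjusted over the list alone; adjusted p = 0.29) and 0 of 9 sigma factor genes (1 lower adjusted over the list alone; adjusted p = 0.423) were called. At an unadjusted p under 0.05 these lists had 1 and 3 members, and DESeq2 called 0 in each. In the 4 iron starvation pairs alone, with the experiment as a block and chosen after seeing the data, pvdS (-1.15 ± 0.20, adjusted p = 0.00734) and fiuI (-0.69 ± 0.15, adjusted p = 0.0231) were lower in the empty vector titles. The other 7 sigma factor genes were not called there, rpoS among them (-0.29 ± 0.14, adjusted p = 0.222), and 2 multidrug efflux genes were higher. DESeq2 called 131 genes, and the count was 76 without transitional growth replicate 6. The iron starvation libraries alone gave 75 (281 with the experiment as a block, 166 higher and 115 lower), low osmolarity alone 17, and heat shock at 50 °C alone 0 with edgeR (383 of 3004 genes at an unadjusted p under 0.05) and 42 with DESeq2.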

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

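All tests of explanations in this part were chosen after the results were seen; the counts over other groupings of libraries were planned. Of 103 list, sigma factor and library values tested for a deviating library, 5 deviated, against 5.15 by chance, about 1 in 20.

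In both anoxic libraries 8 of 12 rRNA features had 0 counts, as had most genes of the 2 phz operons. Reads shared by near-identical copies may have been dropped when these files were made: the ratio of tufA and tufB to fusA1 was at most 0.104 there, against 0.583 to 1.92 in the 45 other libraries. Better depletion of rRNA as the whole cause is excluded, since other 23S rRNA copies held at least 352 counts beside copies at 0, whereas copies differ at most 1.51-fold elsewhere. Lower phenazine expression does not concern the 8 rRNA features at 0, which are part of the pattern itself and so are no test of it. It stays open for the phenazine genes themselves, since 6 of 8 outside the operons were also lower.

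In the tumor libraries pscP (881 and 804 CPM), pelF (626 and 1834), ykgJ (211 and 347), PA14_48840 (191 and 199) and PA14_49500 (196 and 302) exceeded every other library, where they reached at most 12.3 CPM. For pelF and pscP, 12 neighbouring pel and psc genes changed by a median of 0.759 (SD 1.71, 3 called higher). A rise shared alike by all these neighbours was thus not seen. Expression of either operon as the cause is not excluded: the median pools pel and psc genes, some of which rose, and coordinates were not used. Reads of mouse RNA counted at pscP, pelF, ykgJ, PA14_48840 and PA14_49500 could explain the pattern and were not excluded. No other library held more than 0.0345 of the lower tumor level, but the genes were picked for being low there. Higher expression of these genes in the host was not tested.

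The feature PA14_31930 lay at 9.34 to 22.0 CPM (24 to 151 counts) in the 11 libraries titled empty vector and at 0 to 3.17 CPM (0 to 9 counts) in 33 libraries titled wild type, and PA14_20870 at 38.0 to 124 against 1.35 to 9.79 CPM. PA14_35150 and PA14_11230 were also higher, with overlapping ranges. Something the empty vector titles share, such as a plasmid, stays open: the lowest value of 9.34 CPM lies above the wild type range, but the feature was picked for this difference, so the value is no test. The PA14_31930 difference was seen in 9 of 9 experiments with both kinds of title. This follows from the separated ranges for which the feature was picked, so it is no test of a single deviating experiment or condition. That the libraries titled overexpressed share it too is excluded by 2 of 3, which lay within the wild type range (0 and 0.447 CPM for RpoN), while the RpoD title had 11.8 CPM.

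The mean log2 CPM of the AlgU genes was 5.615 in exponential growth replicate 4 (5.882 to 5.969 in the others). The pvdS level was 0.26 CPM in low osmolarity replicate 1 (0 in the others) and 1.063 CPM in transitional growth replicate 3 (0 to 0.124). Both rest on at most 3 counts, which correspond to 0.78 and 1.06 CPM in these 2 libraries. The flagellum mean was 4.643 in transitional growth replicate 4 (5.002 to 5.038). The rpoD level was 552.7 CPM in transitional growth replicate 2 (293.7 to 359.7). Among named genes 50 of 387 tests had a deviating library, against 19.35 by chance. The difference between titles differed between iron starvation, heat shock at 50 °C and low osmolarity for 41 of 4946 genes (16 libraries, 723 at an unadjusted p under 0.05).

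Other groupings of the same libraries were counted for the comparisons with at least 3 libraries per group, 100 groupings each. In each only 1, the real grouping, called as many genes: 1169 against at most 2 in transitional against exponential growth, 1585 against 406 in iron starvation, 316 against 15 in low osmolarity, 2620 against 1862 in heat shock at 50 °C, and 46 against 2 for the titles. With 100 groupings the smallest possible share is 1 in 100. Other groupings of 2 conditions mix them and widen the spread, which favours the real grouping. The counts therefore do not exclude chance. The counts refer to fits of the 2 groups alone, except for the titles. The grouping behind 1862 kept transitional growth replicates 1, 2, 3 and 6 together, and so follows the heat shock in large part.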

How the results depend on the processing

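The fits without some transitional libraries, and those of the anoxic libraries without rRNA, tRNA, tuf and phz genes or for phenazine genes outside the operons, and the block within iron starvation for the titles, were chosen after the results were seen. Of 6510 values of named genes, 6115 kept call and direction, 364 lost the call or weakened, and 31 reversed, 8 of them past the threshold. Of 1162 counts for 66 pairs of a list and a comparison, 982 stayed within 1.5 times and 180 moved. Of 39 list calls, 38 held with RLE and 39 with upper quartile factors. Where 1 library of a group remained, it was assumed to vary like the other groups. The cause of the moves was not tested.

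With each library left out in turn, the counts of called genes ran over these ranges, against the counts in the report: transitional 1165 to 1668, stationary 1984 to 2809, iron starvation 1314 to 1804, low osmolarity 195 to 480, heat shock 42 950 to 1818, heat shock 50 3377 to 3651 (against heat shock 42, 1049 to 2096), low phosphate 913 to 1721, anoxic 1651 to 1937, attachment 241 to 305, biofilm 24 h 540 to 906, biofilm 48 h 6 to 68, tumor 1353 to 2307, RpoN title 15 to 108, titles 34 to 76.

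The replicate numbers were not taken to pair libraries: with 3 or more pairs, the correlations of same-numbered deviations were not all over 0.1 (-0.309 to -0.0566 in iron starvation, -0.189 to 0.0268 in heat shock 50, -0.0984 to 0.0996 in low osmolarity, -0.0150 to 0.428 in transitional growth). Libraries that correlated best with their own number were 0 of 10, 0 of 8, 3 of 6 and 5 of 8. With 2 pairs the values ran from -0.127 to 0.342 (0.128 in biofilm 24 h and 0.342 in biofilm 48 h). With a replicate block the counts were 846 in transitional growth, 698 in iron starvation, 187 in heat shock 42, 2128 in heat shock 50 and 248 against heat shock 42, 739 in low phosphate, 1541 in attachment and 1031 in biofilm 48 h; it moved no other count of called genes by over 1.5 times. No paired analysis was possible for the RpoN titles because the 2 groups share no number in the descriptions and only 1 in the titles of that experiment.

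With the 2 groups alone, counts were 947 in heat shock 42, 1131 between heat shocks, 1599 in attachment, 418 in biofilm 48 h and 35 for the RpoN title. DESeq2 gave 284 in biofilm 48 h and 131 for the titles. Without empty vector titles, low osmolarity gave 68 and heat shock 42 894. Against exponential growth, iron starvation gave 3298, heat shock 42 2664 and low phosphate 2523; against stationary phase, biofilm 48 h gave 772. Without transitional replicates 2 and 6, iron starvation gave 928, heat shock 42 1100 and the RpoN title 56; without 1, 3 and 4, transitional growth gave 520 and the RpoN title 219. Titles within iron starvation gave 75 (281 with the experiment as a block), low osmolarity 17 and heat shock 50 0 with edgeR (383 at an unadjusted p under 0.05, 42 with DESeq2). Of 510 list tests 195 were called with the preset correlation, 8 with an estimated correlation and 237 with fry. Phenazine genes lower in the anoxic libraries were 6 outside the operons, against 20.

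Directions reversed with other reference groups. Against exponential growth: phzS 0.074 in iron starvation, aprA 0.26 in low phosphate, and in biofilm 24 h glpD -0.46, ccpR -1.90, gltG -0.50, purH -0.30, gltK -0.076, prrH 5.40, prrF1 5.31, rmf 1.86, pdhB 1.56, lasB 2.04, sRNA1059 0.89, amiR 0.29, nirG -0.29, napE 0.34, napD 0.41, napF 0.34, pilX -0.10 and pilJ -1.28. Against stationary phase: in biofilm 48 h prrH -1.50, pa1L -0.094, sRNA1059 -0.39, prrF2 -1.145, gnyB 0.42 and napE -0.78, and in the tumor pvdS -1.07, pchE -0.19, pchR -1.20, fptA -2.67 and pchD -3.40.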

Other observations

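The lists described here were chosen after their results were seen, from 510 list tests of which 8 were called also with an estimated correlation. In the anoxic libraries most genes of a mixed list of SOS (DNA damage response) and pyocin genes were higher than in stationary phase. Of 11 SOS and pyocin genes 10 were higher and 1 not called (10 adjusted over the list alone; camera adjusted p = 1.95e-10, and adjusted p = 4.72e-04 with an estimated correlation). The pyocin lysis gene lys stood at 390.2 ± 44.2 CPM (5.27 ± 0.43), and the recombinase gene recA at 703 ± 77.4 against 87.0 CPM (n = 2 each, 3.01 ± 0.42). The repair gene recN (4.20), the pyocin activator gene prtN (3.79) and the repressor gene lexA (3.15) were also higher.

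Alginate genes were higher in 2 further comparisons. In the tumor libraries 12 of 13 were higher and 1 not called (12 adjusted over the list alone; adjusted p = 1.19e-21, and adjusted p = 2.88e-05 with an estimated correlation), with alg44, alg8 and algA higher by 7.16, 5.96 and 5.64. In low phosphate 12 of 13 were higher and 1 not called (12 adjusted over the list alone; adjusted p = 6.21e-10, and adjusted p = 0.0443 with an estimated correlation), with algD at 46.9 ± 26.1 against 0.791 CPM (5.84 ± 0.50). The gene not called was algC in both, which also serves other polysaccharides.

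After the 42 °C shock 7 of 11 oxidative stress genes were higher and 4 not called (7 adjusted over the list alone; adjusted p = 2.58e-05, and adjusted p = 0.0443 with an estimated correlation). The 2 libraries varied. The catalase gene katB stood at 81.5 ± 77.3 against 5.85 ± 1.76 CPM (3.93 ± 0.33). The alkyl hydroperoxide reductase gene ahpF stood at 276 ± 317 against 24.5 ± 6.27 CPM (3.51 ± 0.43). The SEs use a spread estimated over all 16 groups, so they do not show the spread between these 2 libraries. The genes ohr and katA rose by 2.44 and 2.04. In iron starvation 29 of 35 denitrification genes were lower than in transitional growth, 1 higher and 5 not called (31 and 1 adjusted over the list alone; adjusted p = 1.09e-29, and adjusted p = 0.00998 with an estimated correlation). The OD600 and the medium also differed between these groups. In the tumor libraries the efflux pump genes mexA, mexB and oprM changed by -2.43, -2.36 and -1.74 (5 of 7 multidrug efflux genes lower and 2 not called, 5 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.204 with an estimated correlation).

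The 5 transitional libraries differed among themselves. Replicates 2 and 6 correlated across genes at 0.923 to 0.963 with exponential libraries and at 0.901 to 0.932 with replicates 1, 3 and 4, while replicates 1, 3 and 4 correlated with each other at 0.885 or more (0.952 between 1 and 3; replicate 4 had 115397 counts without rRNA); genes are not independent replicates. In a fit with replicates 2 and 6 as a group of their own, they differed from exponential growth in 509 genes (520 where replicates 1, 3 and 4 were left out of the fit). In the first of these fits they differed from replicates 1, 3 and 4 in 297 genes, and in 79 after all were thinned to 115397 counts. Replicate 2 is the only one of the 5 titled empty vector, and replicate 6 is titled wild type. In replicate 2 the chaperone genes dnaK, htpG and groEL stood at 935, 706 and 1996 CPM. The other 4 held at most 88.1, 68.3 and 501 CPM. The cause was not tested.

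Within iron starvation genes of glucose use, picked because they differed, stood higher in libraries titled empty vector than in those titled wild type (n = 4 each). The means were 155 ± 19.5 against 22.3 ± 6.90 CPM for zwf (PA14_23070), for glucose 6-phosphate dehydrogenase, 163 ± 46.4 against 29.8 ± 14.1 CPM for edd, 43.9 ± 14.1 against 6.31 ± 3.64 CPM for edaA, 32.6 ± 9.27 against 4.33 ± 1.32 CPM for pgl, 76.2 ± 11.3 against 10.997 ± 5.303 CPM for gapA (PA14_22890) and 220 ± 86.8 against 48.21 ± 28.88 CPM for gltK. Their title differences were not the same in iron starvation, heat shock at 50 °C and low osmolarity (adjusted p = 0.00381, 0.0087, 0.00876, 0.00317, 0.00386 and 0.0359). In low osmolarity the means were 181.5 against 159.7, 141 against 141, 33.3 against 33.5, 30.3 against 27.5, 34.25 against 36.44 and 89.9 against 61.6 CPM in the same order. After heat shock at 50 °C they were 52.9 against 45.7, 90.2 against 158, 6.64 against 10.3, 5.37 against 7.89, 3.08 against 6.52 and 7.26 against 19.7 CPM.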
